A study of Mus musculus with 18 samples.

How the data were processed

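The samples were hearts of male and female mice, controls or kept under chronic constant hypoxia (CCH) or chronic intermittent hypoxia (CIH), for 1, 2 or 4 weeks, with 2 arrays in each of 9 groups and 18 arrays in all. Each array was a 2-colour cDNA microarray with male heart cDNA in Cy5 and female heart cDNA in Cy3 per the labels. The labels do not say whether the arrays of a group came from separate animals, so the p-values measure the spread between these arrays. They give no batch that covers all arrays.

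The deposited values are log2 ratios of the 2 channels, which the authors scaled so that the mean ratio on the linear scale is 1 on each array. Base 2 was settled from the values, since 2 to the power of the value averages 1 on every array. Background correction, the spot filter and the normalization are not stated in the labels. The labels do not state the direction of the ratio. Male over female was inferred from the sign of the Y-linked gene Eif2s3y. The files hold no coordinates, so none are given. Of 28704 spots, 18511 carried 1 gene symbol, 937 several and 9256 none, 9368 had a value on all 18 arrays and 2289 on none. For 18267 spots the gene identifier was found in the RefSeq table, and 0 symbols were changed.

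Each array was centred on its median, and spots of 1 gene were averaged. Spots with no gene symbol or with several were tested on their own. A unit was tested if it had a value on at least 1 array of each of the 9 groups, which left 10272 units (4279 genes from more than 1 spot, 7577 units with a value on all arrays). With gaps an average can rest on different spots on different arrays. The models were fitted with limma 3.58.1 in R 4.3.3 (lmFit with 9 group means, contrasts.fit, eBayes, prior degrees of freedom 5.95, prior SD 0.269), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were the mean ratio of the control groups and of all groups against 0, CCH minus control, CIH minus control and CCH minus CIH averaged over the 3 durations, each hypoxia against control at each duration, controls at 4 weeks minus 1 week, and an F test of whether the hypoxia effect changes with duration. Counts of arrays that show a direction refer to the arrays of the first-named condition against the mean of the second at the same duration, or to the sign of the ratio where the comparison is with 0. In the alternatives with additive terms or covariates, contrasts.fit is approximate for units with gaps.

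Gene lists were tested with the formula of limma's camera at its preset correlation of 0.01 between genes, adjusted over the 26 of 29 lists with at least 3 measured members, and again with the correlation estimated from the residuals. Counts of members are given over all genes tested and adjusted over the list alone. The ribosomal protein list was matched by symbol and includes the kinase genes Rps6ka5 and Rps6ka6. The proteasome list includes the ubiquitin pathway genes Fbxo32 and Uchl1, and the translation factor list the Y-linked gene Eif2s3y. The other 3 lists (Y-linked genes, Xist and thymus markers) had 1, 0 and 1 measured members, and the result of the first is that of Eif2s3y. An exact permutation of each array's list median within duration has 216 relabellings and a smallest p of 0.00926. Against 0, exact sign flips were used, 64 for the controls (smallest p 0.03125) and 262144 for all arrays. The spread of ratios per array was compared with the same exact permutation. The overlap of the 2 hypoxia responses was compared with 50 simulations of all arrays without any change, and the number of units shared at an unadjusted p under 0.05 with another 20. Figures were drawn with matplotlib 3.10.9.

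Genes were named by a rule. Up to 10 symbols per direction with the largest change were named among those past the threshold, and where fewer than 5 passed, the list was filled up to 5 with the smallest p-values. The 4 members with the smallest p-values of each list past the threshold and 26 genes of hypoxia, sex and heart strain completed it. Of these 26, 13 could be tested. Ddx3y, Kdm5d, Uty, Hba-a1, Myh6, Myh7, Acta1 and Vegfa had no spot with that symbol as its only gene, Mb and Ucp1 had no values, and Xist, Nppa and Hbb-b1 had values on 10, 14 and 2 arrays. The comparisons, tests, lists, this rule and all but the last-named alternatives were fixed before the data were examined. Extending the rule to the ratio over all arrays, and naming the units called at single durations, were decided afterwards.

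The title of 1 array (CIH 1 week replicate 1) gives 1 week of CIH and its source names 2 weeks of CCH. It was grouped by its title, and left out or regrouped as alternatives. Another array, control 2 weeks replicate 1, is named a 2-week control by its title and sources but carries the code 1A, where a week digit in the other coded titles matches the duration. It was kept at 2 weeks and left out as 1 of the alternatives. The A and B letters in the titles do not pair the arrays, with a median correlation of -0.0487 over 21 pairs of groups, so they enter only as an alternative, without the 2 arrays that carry no letter. Other alternatives were no centring, quantile normalization, scaling to a common median absolute deviation, units on all or on at least 9 arrays, single spots, eBayes with robust and trend, arrayWeights, condition and week without interaction, a threshold of 0.10, fry, the estimated correlation, split controls and each array left out in turn. Alternatives added after seeing the data were the removal of 1 or 2 leading components of the within-group residuals, 1 mean for all arrays or for the controls, and the exact tests of list medians. The array scores of the components came from the full ratios, so their removal can also take out a difference between conditions.

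The pipeline was tested on simulated data with the same gaps. Of genes changed 1.5-fold, 2-fold and 4-fold, it called 76.1%, 97.0% and 100% in the control ratio, 31.3%, 94.0% and 100% in CIH minus control and 4.48%, 31.3% and 93.9% in CIH at 2 weeks. Of 520 gene list tests of CIH minus control on simulated data without any change, 2 were called with the preset and 1 with the estimated correlation. Where genes of an array shared a pattern, 0 of 520 were called with either. That pattern was drawn for each gene without regard to the lists, so members of a list did not move together. In the deposited data the erythroid list had an estimated correlation of 0.35 between genes. The rate of false calls in such correlated lists was therefore not measured. These simulations assume independent arrays of equal spread, which the deposited arrays need not have.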

Results

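The series compared hearts of male and female mice after 1, 2 or 4 weeks of chronic constant hypoxia (CCH) or chronic intermittent hypoxia (CIH) with hearts of controls of the same durations. Each of the 18 cDNA arrays held cDNA of a male heart in the dye Cy5 and of a female heart in the dye Cy3. Both hearts came from the same condition and duration, and each value is a log2 ratio of the 2 channels. The labels do not state its direction, which was taken as male over female from the sign of the Y-linked gene Eif2s3y. There were 2 arrays in each of the 9 groups and 6 arrays per condition, and this number limits the precision of every value. Of 28704 spots, 20489 to 24512 had a value on the arrays of 1 week, 15802 to 19720 on those of 2 weeks and 12650 to 17904 on those of 4 weeks. The tests covered 10272 units, of which 6945 were named genes and 3327 were spots that carry no single gene name. A comparison of conditions asks whether the male-to-female ratio changed, and it cannot show in which sex a transcript changed. In a comparison of the ratio itself with 0, sex and dye cannot be separated, because 18 arrays held the male heart in Cy5 and 0 held the female heart in it.

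The ratios of the control hearts address which genes differ between male and female hearts without hypoxia. Eif2s3y, a Y-linked gene for a subunit of a translation initiation factor, had a mean log2 ratio of 1.44 ± 0.15 (SE, n = 6 arrays), which is 2.71-fold more signal from the male hearts. It was positive on 6 of 6 control arrays. That sign set the direction of the ratio, so it is no separate result. Eif2s3y was the only unit past the threshold (limma adjusted p = 0.00135), while 940 units had an unadjusted p under 0.05. The count was 34 without control 1 week replicate 2, 33 with quantile normalization, 21 with arrays scaled to a common spread, and 80 and 25 with 1 and 2 residual components removed. It was 8 with units on at least 9 arrays and 2 without centring. Among X-linked genes that escape X inactivation, the histone demethylase gene Kdm6a had a ratio of -0.57 ± 0.09 (SE, n = 6) and was negative on 6 of 6 arrays, with a limma adjusted p of 0.0956. The RNA helicase gene Ddx3x had a ratio of -0.39 (6 of 6 arrays, adjusted p = 0.297), while Kdm5c was at 0.06 and Usp9x at 0.01. Eif2s3x, another gene of that list, was not tested, because the 4-week controls had no value for it. Its ratios were 0.316 and -0.198 on the controls of 1 week and 0.26 and 0.07 on those of 2 weeks. None of the next genes by p-value passed the test. On the negative side Gsn, which encodes the actin-severing protein gelsolin, was at -0.51 (limma adjusted p = 0.125, 6 of 6 arrays) and Acaa2, an enzyme of fatty acid oxidation, at -0.50 (adjusted p = 0.148, 5 of 6). They were followed by Psap (-0.48, adjusted p = 0.148, 6 of 6) and Vstm4 (-0.65, adjusted p = 0.148, 4 of 4). On the positive side the first were Dus1l (0.42, adjusted p = 0.209, 4 of 5) and Commd7 (0.37, adjusted p = 0.216, 6 of 6). Behind them stood Mosmo (0.54, adjusted p = 0.245, 4 of 4) and Tsc22d4 (0.46, adjusted p = 0.245, 3 of 5). Xist, the RNA that coats the inactive X chromosome of females, had values on 10 of the 18 arrays and ratios of -0.58 to 0.60, so its spot did not separate the sexes.

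In control hearts, 8 of 26 gene lists lay lower in male over female than the other genes by limma's camera test, and no list lay higher. All 8 calls were lost when the correlation between genes was estimated. The antioxidant list then had an adjusted p = 0.521 with an estimated correlation, the X-linked, skeletal muscle and proteasome lists 0.833 and the other 4 lists 0.864. Over all genes no member of these lists passed the test, and the counts that follow are adjusted over the list alone. Of the 4 tested genes that escape X inactivation, which leave out Eif2s3x, 2 (Kdm6a and Ddx3x) fell below 0 (list adjusted p = 0.0366, median ratio -0.19). The call was lost without control 1 week replicate 2, control 2 weeks replicate 1 or control 4 weeks replicate 1 (adjusted p = 0.076, 0.0999 and 0.108), and the median was -0.30 without control 4 weeks replicate 2. Of 61 genes on the ribosomal protein list, which includes the kinase genes Rps6ka5 and Rps6ka6, 3 fell below 0 and 50 were negative (list adjusted p = 0.000287). Among them were Rpsa at -0.54, Rpl11 at -0.58, Rps3a1 at -0.45 and Rps4x at -0.35. Their list median was -0.57 on control 1 week replicate 1 and between -0.19 and 0.14 on the other 5 control arrays. The call was lost without that array (median -0.0099, adjusted p = 0.997) or control 2 weeks replicate 1 (-0.087, adjusted p = 0.104), and the median was -0.25 without control 1 week replicate 2. The genes on the leukocyte and macrophage list were negative in 17 of 17 cases (list adjusted p = 0.0366), with Cxcl12 at -0.27, H2-Eb1 at -0.28, Cd79a at -0.21 and Lyz2 at -0.22. By array, their list median was -0.53 on control 1 week replicate 1 and between -0.21 and 0.16 on the others, above 0 on 2 of them. On the same array the median of the 3 lung markers was -2.09 and that of the cell cycle genes -0.92. The leukocyte call was lost without that array (median -0.063, adjusted p = 0.855), control 2 weeks replicate 1 (adjusted p = 0.176) or control 4 weeks replicate 1 (adjusted p = 0.324), and the median was -0.26 without control 1 week replicate 2 and -0.185 without control 4 weeks replicate 2. On the proteasome list, which includes the ubiquitin pathway genes Fbxo32 and Uchl1, 30 of 38 genes were negative (list adjusted p = 0.000979). Psmb6 was at -0.32, Psmb3 at -0.28, Psmd4 at -0.26 and Psmc2 at -0.25, and the call was lost without control 4 weeks replicate 1. Among antioxidant genes 12 of 18 were negative (list adjusted p = 0.0481), with Prdx2 at -0.27, Prdx3 at -0.33, Txn2 at -0.22 and Gstp1 at -0.32. That call was lost without any 1 of 11 arrays (adjusted p from 0.0503 to 0.201), which were the controls except control 2 weeks replicate 1, the CIH arrays of 1 and 2 weeks, CCH 1 week replicate 2 and CCH 4 weeks replicate 1. By processing, quantile normalization or arrays scaled to a common spread ended the X-linked, leukocyte and antioxidant calls (adjusted p from 0.0559 to 0.0798). With 2 residual components removed the X-linked (median -0.094), proteasome (-0.076) and antioxidant calls (-0.10) were lost, each at an adjusted p = 0.492, and the leukocyte median was -0.25. With units on all arrays the leukocyte (median -0.18, adjusted p = 0.0562) and antioxidant calls (adjusted p = 0.0581) were lost, and the X-linked median was -0.39. The antioxidant call was lost without centring too (adjusted p = 0.0529) and with CIH 1 week replicate 1 regrouped by its source names (adjusted p = 0.0525).

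The other 3 of these lists, of energy metabolism and skeletal muscle, had their lowest list median on 1 control array, control 2 weeks replicate 2, and were called only with the preset correlation (adjusted p = 0.864, 0.864 and 0.833 with an estimated correlation). In oxidative phosphorylation 47 of 65 genes were negative (list adjusted p = 0.00674), with Ndufa13 at -0.39, Cox7a2l at -0.35, Cox7a2 at -0.28 and Ndufb5 at -0.30. The list median was -0.59 on that array and between -0.082 and 0.21 on the other 5. The call was lost without that array (median -0.0016, adjusted p = 0.775), control 1 week replicate 2 (-0.055, adjusted p = 0.217) or control 4 weeks replicate 2 (adjusted p = 0.0881). The median was -0.17 without control 2 weeks replicate 1 and -0.13 without control 1 week replicate 1. Of 22 genes of fatty acid oxidation, 1 fell below 0 adjusted over the list alone (Acaa2) and 16 were negative (list adjusted p = 0.0403), with Lpl at -0.46, Acadvl at -0.32 and Hadhb at -0.26. The list median was -0.585 on control 2 weeks replicate 2 and between -0.23 and 0.41 on the others. The call was lost without that array (median -0.042, adjusted p = 0.451), control 1 week replicate 2 (-0.012, adjusted p = 0.883) or control 4 weeks replicate 1 (-0.055, adjusted p = 0.311). It was also lost without control 4 weeks replicate 2, CCH 1 week replicate 2, CCH 4 weeks replicate 1 or either 2-week CIH array (adjusted p from 0.0518 to 0.099), and the median was -0.20 without replicate 1 of the controls at 1 or at 2 weeks. Markers of skeletal muscle were negative in 8 of 9 cases (list adjusted p = 0.0366), with Myh8 at -0.46, Mylpf at -0.40, Myl1 at -0.30 and Atp2a1 at -0.25. Their list median was -0.52 on control 2 weeks replicate 2 and between -0.33 and 0.068 on the others. The call was lost without that array (median -0.13, adjusted p = 0.334), control 1 week replicate 2 (-0.11, adjusted p = 0.304), either 4-week control (adjusted p = 0.172 and 0.0581) or CCH 1 week replicate 2 (adjusted p = 0.0553). The median was -0.36 without control 2 weeks replicate 1. With 2 residual components removed all 3 calls were lost (medians -0.025, -0.028 and -0.13; adjusted p = 0.661, 0.699 and 0.486). The calls of fatty acid oxidation and skeletal muscle were also lost with quantile normalization (adjusted p = 0.0653 and 0.0634), scaling (adjusted p = 0.0725 and 0.0559) and units on all arrays (adjusted p = 0.198 and 0.0562). In all, the number of lists past the threshold was 2 without control 4 weeks replicate 1, 4 without replicate 2 of the controls at 2 or at 4 weeks and 5 without CCH 1 week replicate 2. It was 3 with quantile normalization or arrays scaled to a common spread, 5 with units on all arrays and 2 with 2 residual components removed.

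**Figure D1:**
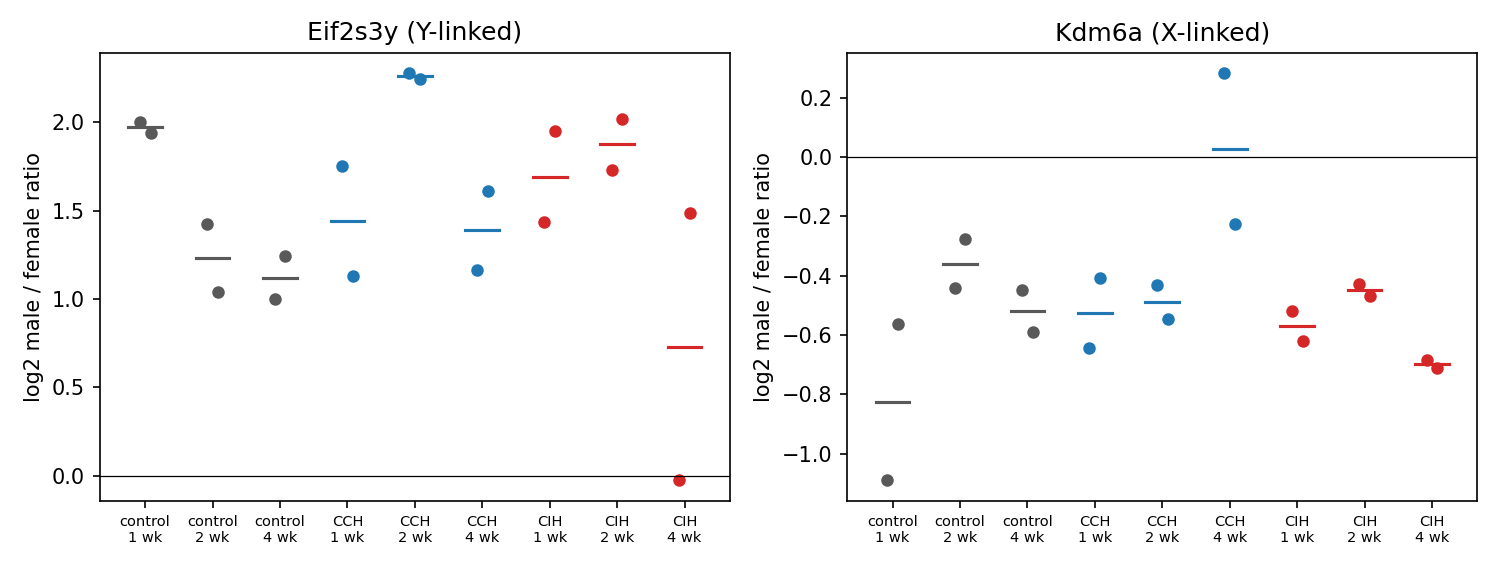
Log2 male-to-female ratio of the Y-linked gene Eif2s3y (left) and the X-linked gene Kdm6a (right) on each array, by condition and duration (wk, weeks), with arrays as points and group means as bars. Eif2s3y lay between 1.00 and 2.28 on 17 arrays and at -0.03 on 1 array of CIH at 4 weeks, and Kdm6a lay below 0 on 17 of 18 arrays.

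Taking all 18 arrays together tests the mean male-to-female ratio over the 3 conditions, which need not differ from 0 in each of them. The ratio of 923 units was above 0 and that of 1922 units below 0 (limma adjusted p under 0.05), among them 596 and 1218 named genes. The median size of these ratios was 0.27 on the log2 scale. The count of 2845 units became 1825 with the A and B letters as a block, 1890 with 1 mean for all arrays, and 4282 and 4598 with 1 and 2 residual components removed. Eif2s3y had a ratio of 1.52 ± 0.09 (SE, n = 18 arrays; adjusted p = 3.44e-07; positive on 17 arrays). Behind it on the positive side stood the epithelial transcription factor gene Spdef (0.62, 11 of 13 arrays), Tsc22d4 (0.58, 15 of 17), the neuropeptide gene Npb (0.56, 17 of 18) and the catenin gene Ctnna2 (0.55, 16 of 17). Pdlim5, a gene of the muscle Z-disc, was at 0.53 (13 of 18). The next were the transporter gene Abca5 (0.52, 13 of 17), Pcsk1n (0.51, 16 of 18), Pogz (0.51, 18 of 18) and Oxnad1 (0.50, 12 of 14). Their adjusted p-values ran from 3.81e-05 for Pogz to 0.0116 for Pdlim5. The largest negative ratios were those of Tmem256 (-0.74, 17 of 18 arrays), Zfp873 (-0.73, 15 of 18), Rpl11 (-0.72, 16 of 18), and the zinc transporter gene Slc39a4 (-0.68, 15 of 18). Atpif1, the inhibitor of mitochondrial ATP synthase, was at -0.68 (15 of 18). The list of 10 closed with Ube2l6 (-0.65, 12 of 18), the stress gene Gadd45b (-0.65, 15 of 17), Gsn (-0.65, 18 of 18), the complement gene C1qa (-0.64, 14 of 18) and Rpsa (-0.63, 16 of 18). Their adjusted p-values ran from 1.37e-05 for Gsn to 0.0139 for Ube2l6. The X-linked genes did not move in the same direction. Kdm6a (-0.49, 17 of 18, adjusted p = 9.5e-05) and Ddx3x (-0.32, 17 of 18, adjusted p = 0.00265) were lower in male over female. Kdm5c was higher (0.30, 11 of 17, adjusted p = 0.0362) and Usp9x was at 0.14 (adjusted p = 0.11). Eif2s3x, which was not tested, was mostly above 0, with ratios from -0.426 on CCH 1 week replicate 1 to 1.46 on CIH 2 weeks replicate 2.

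Over all arrays, 3 gene lists lay lower in male over female than the other genes by the camera test. All 3 calls were lost at an adjusted p = 0.986 (ribosomal proteins and leukocytes) and 0.275 (antioxidant genes) with an estimated correlation. Of 61 genes on the ribosomal protein list, 28 fell below 0 and 2 rose above it over all genes. Adjusted over the list alone, 34 fell and 2 rose (list adjusted p = 1.56e-05), with Rps12 at -0.53 and Rps21 at -0.59. Of 17 genes on the leukocyte and macrophage list, 9 fell over all genes and 10 adjusted over the list alone (list adjusted p = 0.00213). The complement gene C1qa was at -0.64, C1qb at -0.37, the receptor adaptor Tyrobp at -0.33 and the chemokine gene Cxcl12 at -0.23. Of 18 antioxidant genes, 10 fell over all genes, and 10 fell and 1 rose adjusted over the list alone (list adjusted p = 0.0473). Nqo1 was at -0.44, the peroxiredoxin gene Prdx2 at -0.34, the thioredoxin gene Txn2 at -0.26 and the glutathione transferase gene Gstp1 at -0.40. The antioxidant call was also lost without any 1 of 9 arrays (adjusted p from 0.0635 to 0.161). These were control 2 weeks replicate 2, both 4-week controls, CCH 1 week replicate 1, replicate 2 of CCH at 2 and 4 weeks, CIH 1 week replicate 2, CIH 2 weeks replicate 1 and CIH 4 weeks replicate 2. By processing, it was lost without centring (adjusted p = 0.0566), with units on all arrays (adjusted p = 0.0591) and with 2 residual components removed (adjusted p = 0.104). An exact test that flips the sign of each array's list median (262144 sign patterns) gave an adjusted p = 0.00767 for each of the 3. It asks whether the list medians differ from 0, not whether a list lies lower than the other genes. A dye effect shared by the 18 arrays could pass it too.

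**Figure D2:**
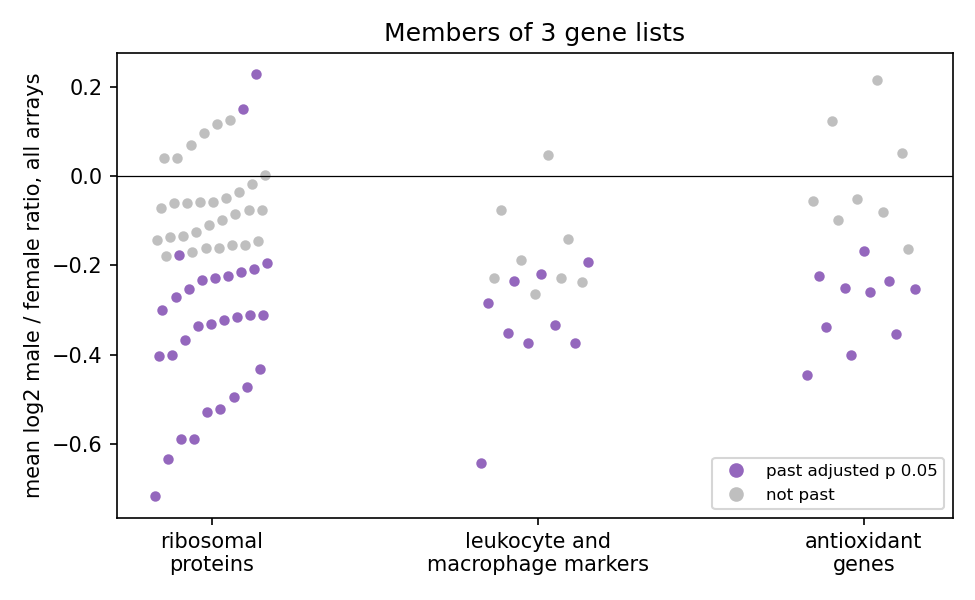
Mean log2 male-to-female ratio over all 18 arrays of each measured gene on the ribosomal protein (61), leukocyte and macrophage (17) and antioxidant (18) lists. Each point is a gene, drawn beside its neighbours only to keep the points apart. Purple points passed an adjusted p of 0.05 over all genes. Of the purple points, 28, 9 and 10 lie below 0 and 2, 0 and 0 above it.

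Constant hypoxia against control asks whether CCH changed the male-to-female ratio. No named gene did so by limma, with 0 of 10272 units past the threshold and a smallest adjusted p of 0.699. At an unadjusted p under 0.05 there were 649 units, where 513.6 are expected by chance. The genes with the smallest p-values all had an adjusted p of 0.699. On the positive side they were Vstm4 (0.79 ± 0.16 SE, 4 of 5 CCH arrays), the mitochondrial ribosomal gene Mrpl40 (0.73 ± 0.16, 6 of 6) and the fatty acid desaturase gene Fads1 (0.50 ± 0.13, 6 of 6). Tut7 (0.58 ± 0.15, 3 of 5) and Thra, the thyroid hormone receptor alpha gene (0.64 ± 0.17, 6 of 6), came next. On the negative side stood Grhpr (-0.70 ± 0.16, 5 of 5), Tafa5 (-0.72 ± 0.16, 5 of 5), the mitochondrial ribosomal gene Mrps28 (-0.50 ± 0.12, 4 of 6), Mzt1 (-0.65 ± 0.15, 5 of 5) and Tspan15 (-0.48 ± 0.12, 5 of 5). As groups, 2 lists were lower by the camera test, without a member past the test over all genes or over the list alone. Both calls were lost at an adjusted p = 0.752 with an estimated correlation. On the ribosomal protein list 52 of 61 genes were negative (median -0.16, list adjusted p = 0.00154, Rps12 at -0.58, Rps23 at -0.52, Rpl41 at -0.42, Rps9 at -0.40). Of the genes of the extracellular matrix 22 of 27 were negative (median -0.12, list adjusted p = 0.0361), among them the proteoglycans Dcn (-0.34), Bgn (-0.34) and Lum (-0.33) and fibronectin, Fn1 (-0.38). The ribosomal call was lost without control 1 week replicate 2 (median -0.041, adjusted p = 0.762) or replicate 2 of the controls at 2 or 4 weeks (adjusted p = 0.0619 and 0.114), and its median was -0.27 without control 1 week replicate 1. The call of the extracellular matrix was lost without any 1 of 7 arrays (adjusted p from 0.0578 to 0.217), and its median was -0.19 without CCH 1 week replicate 1. The 7 were control 1 week replicate 1, control 2 weeks replicate 1, control 4 weeks replicate 2 (median -0.079), CCH 1 week replicate 2, CCH 2 weeks replicate 2, CCH 4 weeks replicate 1 (median -0.073) and CIH 2 weeks replicate 2. The number of lists was 5 without control 1 week replicate 1 or 2, 7 and 4 without control 2 weeks replicate 1 and 2, 0 without control 4 weeks replicate 2 and 1 without CIH 2 weeks replicate 2. It was 0 with arrays scaled to a common spread (ribosomal median -0.072, adjusted p = 0.091; extracellular matrix adjusted p = 0.0821) or units on all arrays (both at an adjusted p = 0.0512), 4 with CIH 1 week replicate 1 regrouped by its source names or 2 residual components removed and 7 with the A and B letters as a block. Without CCH 4 weeks replicate 1 or with 2 residual components removed, 1 unit passed.

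Intermittent hypoxia against control asks the same of CIH. Genes of red blood cells lay lower in male over female as a group under CIH by the camera test. The call was lost at an adjusted p = 0.82 with an estimated correlation, and the exact permutation of list medians within duration gave p = 0.0278 (two-sided, smallest possible 0.00926) and 0.722 after adjustment over 26 lists. Of 17 measured erythroid genes, 13 were negative and 8 fell adjusted over the list alone, though 0 passed over all genes (list median -0.84, list adjusted p = 2.26e-05). Slc4a1, the anion exchanger of the red cell membrane, fell by 1.74 ± 0.37 (SE, limma adjusted p over all genes 0.0521, 5 of 6 CIH arrays). Alas2, the first enzyme of heme synthesis in red cells, fell by 1.73 ± 0.44 (0.0661, 6 of 6), and Fech, the last enzyme of that pathway, changed by -1.25 ± 0.31 (0.0634, 5 of 6). The embryonic globin genes Hbb-bh1 (-1.52 ± 0.36, 0.0565, 5 of 6) and Hba-x (-1.28 ± 0.33, 0.0686, 5 of 6) were among the 8 too. The others were Bpgm, the enzyme that makes the oxygen-affinity regulator of hemoglobin (-1.20 ± 0.27, 0.0521, 6 of 6), the carbonic anhydrase gene Car2 (-1.20 ± 0.36, 0.142, 3 of 4) and the biliverdin reductase gene Blvrb (-0.94 ± 0.16, 0.0521, 6 of 6). The transcription factor genes Klf1 (0.03) and Gata1 (0.14), Car1 (0.02) and Prdx2 (-0.04), which is also on the antioxidant list, were near 0. Sptb, the gene of red cell beta spectrin, was at 0.53 (adjusted p = 0.338, higher on 2 of 4 CIH arrays), against the direction of the list. The list median per array averaged 0.14 ± 0.27 (SD, n = 6) in controls, 0.05 ± 0.69 under CCH and -0.57 ± 0.41 under CIH. The camera test called the list in all 27 settings and leave-outs tried with the preset correlation, with medians of -1.05 to -0.15. The median was -0.49 with arrays scaled to a common spread and -0.15 with 2 residual components removed. The adult globin genes Hbb-b1 and Hba-a1 could not be followed as named genes. Hbb-b1 had values on 2 arrays, and no spot with a single gene name carried the symbol Hba-a1. Spots with several gene names were not part of the list.

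**Figure D3:**
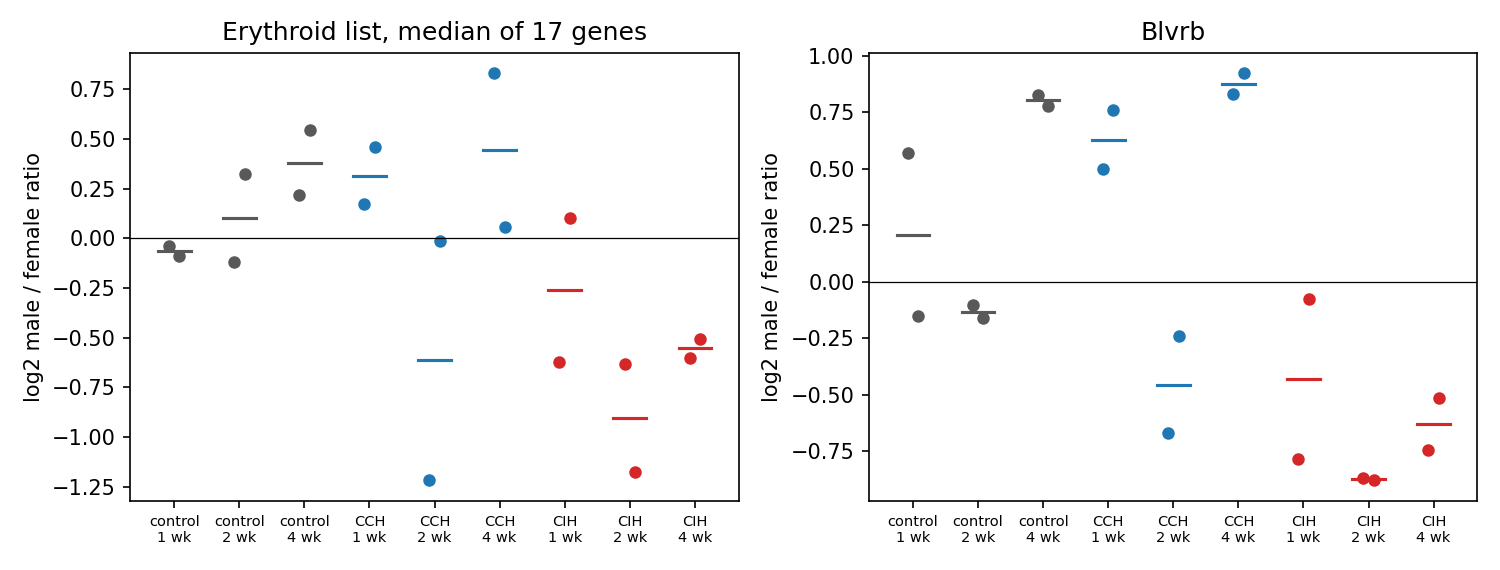
Median log2 male-to-female ratio of the 17 erythroid genes (left) and the ratio of the list's gene Blvrb (right) on each array, by condition and duration (wk, weeks; CCH, constant hypoxia; CIH, intermittent hypoxia), with arrays as points and group means as bars. The list medians lie between -0.12 and 0.54 in controls, between -1.22 and 0.83 under CCH and between -1.18 and 0.10 under CIH.

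Over all genes, 1 unit passed between CIH and control, Phtf1, which encodes a membrane protein best known from testis (-1.64 ± 0.20 SE, limma adjusted p = 0.00538, 5 of 6 CIH arrays). Its spots differed in coverage. The first had values on 17 arrays (-1.73 ± 0.34 on its own, adjusted p = 0.0427) and the second on 12, with 2 of the 6 CIH arrays among them. There were 1307 units at an unadjusted p under 0.05, and at an adjusted p under 0.10 there were 290 units lower and 23 higher. Genes just short of the threshold were Rab23 (-1.16 ± 0.21), the nuclear receptor gene Nr2f2 (-1.35 ± 0.25) and Wdr5b (-1.22 ± 0.23). Each had a limma adjusted p of 0.0521 and was lower on 6 of 6 arrays. In 6 differences between arrays of the same control or CCH group, which hold no CIH array, they followed the mean of the erythroid genes. There r was 0.966 for Rab23, 0.958 for Nr2f2 and 0.933 for Wdr5b, and 0.734 for Phtf1. On the higher side the nearest were Ak7 (0.61 ± 0.14, adjusted p = 0.0564, 6 of 6) and the cohesin gene Smc1a (0.65 ± 0.15, adjusted p = 0.0565, 6 of 6). Below them came Ska1 (0.54 ± 0.13, adjusted p = 0.0605, 5 of 6), the kinesin gene Klc1 (0.63 ± 0.15, adjusted p = 0.0616, 5 of 6) and Rabepk (0.56 ± 0.14, adjusted p = 0.0629, 6 of 6). Many units share an adjusted p of 0.0521, and the count moves with single arrays. It was 305 without control 2 weeks replicate 1, 254 and 251 without CCH 2 weeks replicate 1 and 2 and 207 without CIH 1 week replicate 2. It was 89 without CIH 4 weeks replicate 2, 3 without control 1 week replicate 2 and 2 without control 4 weeks replicate 1. By processing, it was 202 with the A and B letters as a block, 199 with single spots, 192 without centring (191 of them lower), 109 with units on all arrays and 77 with robust eBayes and trend. No unit passed with arrays scaled to a common spread, with array weights, with condition and week as additive terms or with the leading residual component removed.

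Another 3 lists were higher under CIH by the camera test, all genes of energy metabolism or protein folding. All 3 calls were lost at an adjusted p = 0.82 with an estimated correlation. Of 14 genes of the citric acid cycle 13 were positive (median 0.33, list adjusted p = 0.00222), with Dld at 0.50, Idh3a at 0.38, Mdh2 at 0.36 and Ogdh at 0.35. None of them passed over all genes or over the list alone. Of 22 genes of fatty acid oxidation 17 were positive (median 0.16, list adjusted p = 0.0265), with Lpl at 0.64, Pdk4 at 0.42 and Acadl at 0.38. The only member past the test over the list alone was Acads, which fell by 0.67 (adjusted p over all genes 0.0822, 6 of 6 CIH arrays). Acads also followed the mean of the erythroid genes over 6 differences between arrays of the same control or CCH group (r = 0.79). Of 18 heat shock genes 15 were positive (median 0.14, list adjusted p = 0.0265), with Hsph1 at 0.50, Hspd1 at 0.40, Hspa8 at 0.33 and Hspa5 at 0.29, and again none passed. The call of fatty acid oxidation was lost without control 1 week replicate 2 (median 0.083, adjusted p = 0.359), control 2 weeks replicate 2 (0.095, adjusted p = 0.113) or CIH 4 weeks replicate 1 (0.081, adjusted p = 0.249). It was also lost without CCH 1 week replicate 2, CIH 1 week replicate 1 or CIH 2 weeks replicate 1 (adjusted p from 0.0555 to 0.0839), and its median was 0.25 without CIH 4 weeks replicate 2. The heat shock call was lost without control 2 weeks replicate 2 (median 0.091, adjusted p = 0.113), control 4 weeks replicate 1, CIH 1 week replicate 1, CIH 2 weeks replicate 2 or CIH 4 weeks replicate 1 (adjusted p from 0.0672 to 0.13). By processing, the call of fatty acid oxidation was lost with CIH 1 week replicate 1 regrouped (adjusted p = 0.0542), and that of heat shock with the same regrouping, quantile normalization or scaling (adjusted p = 0.0684, 0.0878 and 0.0836). With 2 residual components removed all 3 calls were lost (adjusted p = 0.793 for the citric acid cycle, 0.618 for fatty acid oxidation and 0.793 for heat shock) and their medians turned negative, the lowest being -0.08 for fatty acid oxidation. The number of lists past the threshold was 11 without control 1 week replicate 1, 9 and 2 without control 2 weeks replicate 1 and 2, 2 without CIH 1 week replicate 1, and 2 and 8 without CIH 4 weeks replicate 1 and 2. It was 7 with 2 residual components removed.

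The direct comparison of CCH with CIH asks whether the 2 kinds of hypoxia differ in the male-to-female ratio. Phtf1 was 1.56 ± 0.20 (SE) higher under CCH (limma adjusted p = 0.0101, 6 of 6 CCH arrays) and was the only unit past the threshold, with 953 units at an unadjusted p under 0.05. The first spot of Phtf1 had values on 5 CCH and 6 CIH arrays and the second on 6 and 2. Its averages therefore rest partly on different spots in the 2 conditions, and no unit passed with single spots. By the camera test 6 gene lists differed, none of them with an estimated correlation (each at an adjusted p = 0.874 with an estimated correlation). Of 17 erythroid genes, 8 rose under CCH against CIH adjusted over the list alone and 0 over all genes (list median 0.27, mean 0.58, list adjusted p = 2.26e-06). The list passed with any 1 array left out, but its median then ranged from 0.17 to 0.92. It was 0.92 without CCH 2 weeks replicate 1, 0.87 without control 4 weeks replicate 2, 0.72 and 0.51 without CIH 2 weeks replicate 1 and 2, 0.57 without control 2 weeks replicate 1, 0.56 without CIH 4 weeks replicate 1, 0.44 without CCH 1 week replicate 2 and 0.17 without CIH 1 week replicate 1. With units on all arrays or the A and B letters as a block it was 0.87. Among the 8 were Blvrb (0.99, adjusted p over all genes 0.0681, 6 of 6 CCH arrays), Slc4a1 (1.61, 0.145, 5 of 6), Car2 (1.46, 0.173, 4 of 5) and Bpgm (0.87, 0.223, 6 of 6). Lists of mitochondrial energy metabolism were lower under CCH than under CIH by the camera test, though again not with an estimated correlation (adjusted p = 0.874 with an estimated correlation). Of 65 genes of oxidative phosphorylation 60 were negative (median -0.18, list adjusted p = 2.26e-06), with Ndufa11 at -0.47, Ndufs7 at -0.42, Ndufc1 at -0.40 and Ndufb6 at -0.28. The call of oxidative phosphorylation was lost with 2 residual components removed (median -0.067, adjusted p = 0.196) and with the A and B letters as a block (-0.091, adjusted p = 0.217), and the median was -0.11 with arrays scaled to a common spread and -0.12 with quantile normalization. Of 14 genes of the citric acid cycle 12 were negative (median -0.26, list adjusted p = 0.0444), with Idh3g at -0.37, Sucla2 at -0.34, Ogdh at -0.32 and Dlat at -0.28. Genes on the ribosomal protein list were negative in 50 of 61 cases (median -0.13, list adjusted p = 0.00459), with Rps14 at -0.47, Rps27l at -0.34, Rpl7a at -0.33 and Rpl14 at -0.31. Immediate early genes were negative in 11 of 13 cases (median -0.20, list adjusted p = 0.0444), with Nr4a1 at -0.70, Btg2 at -0.63, Jun at -0.55 and Fosl2 at -0.50. No member of these 4 lists passed over all genes or over the list alone, and all 4 had an adjusted p = 0.874 with an estimated correlation. The citric acid cycle call was lost without any 1 of 10 arrays (adjusted p from 0.0511 to 0.618), with medians from -0.28 to -0.11, and its median was -0.39 without CIH 4 weeks replicate 2. Those 10 were the controls of 1 and 4 weeks, CCH 1 week replicate 1, CCH 2 weeks replicate 1, CCH 4 weeks replicate 2, CIH 1 week replicate 1, CIH 2 weeks replicate 2 and CIH 4 weeks replicate 1. By processing, it was lost with 2 residual components removed (median -0.034, adjusted p = 0.938), the letters as a block (-0.054, adjusted p = 0.906), scaling (adjusted p = 0.151), quantile normalization (adjusted p = 0.113), units on all arrays (adjusted p = 0.102) and CIH 1 week replicate 1 regrouped (adjusted p = 0.0698). The call of the immediate early genes was lost without any 1 of 9 (adjusted p from 0.0582 to 0.292; medians from -0.23 to -0.12). Those 9 were control 2 weeks replicate 1, control 4 weeks replicate 1, CCH 1 week replicate 1, CCH 2 weeks replicate 1, CCH 4 weeks replicate 2, CIH 1 week replicate 2, both CIH arrays of 2 weeks and CIH 4 weeks replicate 1. That call was also lost with the letters as a block (adjusted p = 0.443), 2 residual components removed (adjusted p = 0.155), units on all arrays (median -0.12, adjusted p = 0.131) and CIH 1 week replicate 1 regrouped (adjusted p = 0.0819). The ribosomal call was lost without replicate 2 of CIH at 2 or 4 weeks (adjusted p = 0.117 and 0.137), and its median was -0.073 without CCH 4 weeks replicate 1. Scaling ended it (median -0.065, adjusted p = 0.151), and the median was -0.22 with 2 residual components removed and -0.21 with the letters as a block.

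Of 29 cell cycle genes 21 were positive and 2 rose under CCH against CIH adjusted over the list alone (median 0.08, list adjusted p = 0.0415; adjusted p = 0.874 with an estimated correlation), with Rrm1 at 0.81, Mcm3 at 0.65, Cenpa at 0.45 and Mcm6 at 0.35. The cell cycle list passed in 15 of 27 settings and leave-outs, and its median turned negative with the letters as a block (-0.042, adjusted p = 0.906) and with 2 residual components removed (-0.013, adjusted p = 0.559). Scaling (median 0.046, adjusted p = 0.135) and quantile normalization (adjusted p = 0.113) ended the call, and the median was 0.045 with units on all arrays and 0.20 with CIH 1 week replicate 1 regrouped. The call was also lost without CIH 1 week replicate 2 (median 0.0063, adjusted p = 0.48), CIH 2 weeks replicate 1 (0.011), CIH 4 weeks replicate 1 (0.014), CCH 1 week replicate 1, CCH 2 weeks replicate 1 (0.045), CCH 4 weeks replicate 2 (0.046) or either 4-week control (0.077 and 0.050). The median was 0.12 without CCH 2 weeks replicate 2, 0.14 without CCH 4 weeks replicate 1, 0.16 without CIH 1 week replicate 1 and 0.17 without CIH 4 weeks replicate 2. Rrm1 and Mcm3 are also among the units lower under CIH than in controls at an adjusted p under 0.10, and over 6 differences between arrays of the same control or CCH group they followed the erythroid mean (r = 0.81 and 0.717).

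Between CCH and CIH, the exact permutation within duration gave p = 0.0556 for the erythroid list and p = 0.037 for oxidative phosphorylation, both 0.642 after adjustment over 26 lists. Of 100 splits of the CCH and CIH arrays within duration, 14 gave a list statistic for oxidative phosphorylation as large as the real -5.23. On the higher side, genes short of the threshold were Pabpc1 (1.00, adjusted p = 0.134, 5 of 6 CCH arrays) and, both at an adjusted p of 0.145, Cfap36 (1.13, 6 of 6) and Rai14 (1.41, 6 of 6). On the lower side they were Mrps28 (-0.55, 4 of 6), Trib2 (-0.63, 5 of 6), Tafa5 (-0.74, 5 of 5) and the clock gene Nr1d2 (-0.56, 6 of 6), all at an adjusted p of 0.145. Ska1 was at -0.55 (adjusted p = 0.155, 6 of 6). Over 6 differences between arrays of the same control or CCH group, Pabpc1, Cfap36 and Rai14 followed the mean of the erythroid genes (r = 0.728, 0.904 and 0.866). The count of units was 196 without CCH 2 weeks replicate 1, 3 without CIH 1 week replicate 2 and 2 without control 1 week replicate 1 or 2 or CCH 4 weeks replicate 1 or 2. It was 0 without CCH 1 week replicate 2, CCH 2 weeks replicate 2, CIH 1 week replicate 1, CIH 2 weeks replicate 2 or CIH 4 weeks replicate 1. By processing, it was 0 with scaling, single spots, additive terms or the A and B letters as a block, 2 with robust eBayes and trend and 3 with 1 residual component removed. The count of lists was 11 without CCH 1 week replicate 2 and 3 without control 4 weeks replicate 1, CCH 1 week replicate 1, CCH 2 weeks replicate 1 or CIH 2 weeks replicate 2. It was 3 with scaling and 2 with the letters as a block.

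By duration, with 2 arrays against 2, few genes passed. After 2 weeks of CCH the ratio of Pgrmc1, which encodes a heme-binding membrane protein, fell by 1.61 ± 0.23 (SE, limma adjusted p = 0.0248), with a mean ratio of -1.39 against 0.22 in controls. At the same time 1 spot without a gene name changed by -1.50 ± 0.20 (adjusted p = 0.0248). After 2 weeks of CIH Phtf1 fell by 2.74 ± 0.34 (adjusted p = 0.00843), with a mean ratio of -2.58 against 0.16 in controls. These 3 units were chosen after their values were seen. No unit passed after 1 or 4 weeks of CCH (632 and 1549 at an unadjusted p under 0.05) or of CIH (240 and 836). After 2 weeks the unadjusted counts were 964 for CCH and 2331 for CIH. A limma F test for a change of the hypoxia effect with duration called 0 units (1332 at an unadjusted p under 0.05; smallest adjusted p 0.0955). The effects at 2 weeks are therefore not shown to differ from those at other durations. Control hearts at 4 weeks against 1 week gave 0 units (459 at an unadjusted p under 0.05). The 2 CCH calls at 2 weeks were lost without either 2-week control array, either 2-week CCH array, CCH 4 weeks replicate 1, either 1-week CIH array or either 2-week CIH array. The CIH count at 2 weeks was 6 and 0 without control 2 weeks replicate 1 and 2. That of CIH at 4 weeks was 162 and 155 without CCH 2 weeks replicate 1 and 2 and 1 without either CCH array of 4 weeks. That of CCH at 4 weeks was 32 and 2 without CCH 4 weeks replicate 2 and 1, 2 without either 2-week control and 11 without control 4 weeks replicate 2. Without control 1 week replicate 2 there were 2 calls each for CCH and CIH at 1 week and for controls at 4 weeks against 1. Without CCH 1 week replicate 2 there were 2 for CCH at 1 week, and without CCH 4 weeks replicate 1 the F test called 1. By processing, the 2 calls of CCH at 2 weeks became 7 with arrayWeights, 1 with units on all arrays and 0 with CIH 1 week replicate 1 regrouped, the letters as a block or residual components removed. The 1 call of CIH at 2 weeks became 157 with arrayWeights, 3 with scaling and 0 with single spots or residual components removed.

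Of 26 genes of hypoxia, sex and heart strain chosen to be followed in every comparison, 13 could be tested, and 0 of these passed between a kind of hypoxia and control by limma. At an unadjusted p under 0.05 there were 0 under CCH and 3 under CIH (Alas2, Pdk4 and Slc2a1). Under CIH the glucose transporter gene Slc2a1 had a change of -0.47 ± 0.14 (SE, limma adjusted p = 0.123, lower in 6 of 6 arrays). Lactate dehydrogenase, Ldha, had a change of 0.26 (adjusted p = 0.455), Pgk1 of 0.20, Hmox1 of -0.01, Bnip3 of 0.06 and the transferrin receptor gene Tfrc of 0.25. Under CCH these were -0.15 for Slc2a1, 0.32 for Ldha (adjusted p = 0.749), 0.07 for Bnip3 and 0.20 for Hmox1. The natriuretic peptide gene Nppb changed by -0.40 under CCH and -0.22 under CIH, and the calcium pump gene Atp2a2 by 0.20 and 0.23. The collagen genes Col1a1 and Col3a1 changed by -0.07 and -0.10 under CCH and by -0.02 and -0.11 under CIH, and Pdk4 by 0.27 and 0.42. Over all arrays Col3a1 (0.19, adjusted p = 0.039, 12 of 18 arrays) and Pdk4 (0.24, adjusted p = 0.017, 11 of 18) were higher in male over female. The lists of targets of the hypoxia-inducible factor (26 genes, median 0.07 under CCH and 0.08 under CIH) and of glycolysis (18 genes, 0.06 and 0.01) did not pass the camera test in any comparison. By camera, neither did the lists for the fetal and hypertrophic program (12 genes, 0.07 and 0.01), the sarcomere (9 genes, 0.11 and 0.22), calcium handling (12 genes, 0.13 and 0.18) and endothelium (17 genes, -0.11 and 0.01). Also without a call were those for smooth muscle (3 genes, 0.07 and -0.03), lung (3 genes, 0.18 and -0.07) and fat tissue (5 genes, -0.02 and -0.01). The lists for apoptosis (14 genes, 0.02 and 0.09), circadian genes (7 genes, -0.13 and -0.05) and translation factors (44 genes, 0.02 and 0.07) did not pass camera either. The mixed form of fry called translation factors in the control ratio (adjusted p = 0.00617). That list holds the Y-linked gene Eif2s3y, the only unit past the threshold there by limma. Fry in 1 direction did not call the list in the control ratio (adjusted p = 0.481). Whether the mixed call holds without Eif2s3y was not tested. Over all arrays the mixed form called hypoxia-inducible factor targets (adjusted p = 5.36e-06), glycolysis, sarcomere, endothelium, apoptosis, circadian genes and translation factors. There it did not call the fetal program, calcium handling, lung or fat tissue. It called most lists there, where 2845 of 10272 units were off 0, so a call says little about a particular list. Fry in 1 direction called none of the lists named here over all arrays (adjusted p = 0.484 for hypoxia-inducible factor targets and 0.538 for glycolysis).

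The 2 hypoxia responses were compared across genes, since both rest on the same controls. The correlation across genes of the change under CCH with that under CIH was r = 0.575, against 0.505 ± 0.0109 (SD) in 50 simulations of all arrays without any change, where both responses again shared their controls. The covariance was 0.0361, against 0.0165 in these simulations. When each response was set against its own 3 control arrays, r was 0.106 or 0.0898, depending on which controls went to which. At an unadjusted p under 0.05, 101 units were higher and 82 lower under both, against means of 53.8 and 57.1 in another 20 such simulations. Genes are not independent replicates, the simulations treat them as if they were, and no p-value is given for these values. The spread of the log2 ratios over genes was 0.34 ± 0.104 (SD, n = 6 arrays) in controls, 0.443 ± 0.13 under CCH and 0.415 ± 0.107 under CIH. The differences were 0.103 (exact permutation p = 0.102, adjusted 0.306) for CCH against control and 0.0744 (exact permutation p = 0.278, adjusted 0.417) for CIH against control. It was 0.0285 (exact permutation p = 0.667, adjusted 0.667) between CCH and CIH. The last became -0.000785 without CCH 4 weeks replicate 1.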

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

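Among the tests of this part, that of leukocyte markers, that of the largest list statistic per split and that of single arrays in the list medians other than the erythroid and leukocyte ones were chosen only after the result was seen.

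On the array of CIH at 4 weeks replicate 1, the log2 ratio of Eif2s3y was -0.026, while the other 5 CIH arrays lay between 1.43 and 2.02. The gap to the nearest of them was 0.714 of the group's range, above the limit for 6 arrays; chance exceeds that limit in about 1 of 20 groups, and it was exceeded in 4 of 90 groups of 6 arrays. The spot with the larger ratios, 10033, had no value on that array, so its value comes from spot 12430 alone. Among control arrays, the list median of oxidative phosphorylation was -0.594 on control 2 weeks replicate 2, with the others between -0.082 and 0.21 (gap 0.639 of the range). On control 1 week replicate 1 the median of the 3 lung markers was -2.09, with the others between -0.22 and 0.34 (gap 0.769), and that of the cell cycle genes was -0.921, with the others between -0.020 and 0.50 (gap 0.633).

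CCH and CIH differed by a direct test in the ratio of Phtf1, which was 1.56 higher under CCH. Its second spot had values on 6 CCH arrays but on 2 CIH arrays, and no unit passed with single spots. Of 100 splits of these arrays within duration, the real one included, 6 gave at least 1 call; the highest of the other splits gave 110, so chance is not excluded for the count. By the camera test 6 gene lists differed in the same comparison, none of them with an estimated correlation (adjusted p = 0.874 with an estimated correlation for each), with median changes of 0.27 for the erythroid genes (0.17 to 0.92 with 1 array left out), -0.18 for oxidative phosphorylation, -0.26 for the citric acid cycle, 0.077 for the cell cycle, -0.20 for immediate early genes and -0.13 for ribosomal proteins. As many lists came out of 29 of 100 splits, with 10 as the highest of the others, so chance is not excluded for their number either.

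The erythroid genes, lower in male over female under CIH by the camera test (adjusted p = 0.82 with an estimated correlation), are the list that moved most. Taken alone it was reached by 3 of 100 splits within duration (real statistic -4.92, highest of the others -5.04), but 56 of 100 splits gave a statistic that large in some list (highest 9.74), so chance is not excluded for the list that moved most of 26. No single array made it, since with any 1 array left out the median change was at least as low as -0.64. With 2 leading residual components removed the median change shrank from -0.84 to -0.15, although the list stayed past the threshold. The array scores of these components were taken from the full ratios, which hold the difference between CIH and control. A change under CIH in the same genes would shrink too, so this removal cannot decide whether a pattern shared by many genes of an array explains the list. More blood cells of every kind in the RNA of the female hearts, or fewer in that of the male hearts, stays open. The erythroid genes changed by -0.71 ± 0.178 (SE) per array and the genes on the leukocyte and macrophage list by -0.19 ± 0.151. This difference was too imprecise to decide. That list also holds macrophage genes, so it does not measure blood cells alone. A response to CIH that differs between the sexes stays open and untested.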

How the results depend on the processing

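The removal of 1 or 2 residual components, the single mean for all arrays and the exact tests of list medians were chosen only after the results were seen. Among called lists, the medians of fatty acid oxidation, heat shock and the citric acid cycle in CIH against control turned negative with 2 components removed (lowest -0.076, -0.023 and -0.030). That of the cell cycle in CCH against CIH did so with 2 components removed or the letter block (lowest -0.042). The other 19 called lists kept their direction in 27 settings and leave-outs, not all of which could change it. Leaving out an array outside a comparison can move a list median only through the units tested. Leaving out CIH 1 week replicate 1 is counted under 2 of the settings. Most counts depend on the processing, and the cause was not tested except that many units share an adjusted p near 0.05 in CIH against control. Signal over background is not in the files, so its limit on weak spots is unknown.

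Units called in CIH against control numbered 1, and 192 without centring (191 of them lower), 109 with units on all arrays, 199 with single spots, 77 with robust eBayes and trend, 202 with the letter block, 313 at a threshold of 0.10, and 0 with scaling to a common spread, arrayWeights, additive terms or 1 component removed (limma; 1307 at an unadjusted p under 0.05 in the reported fit). CCH against CIH gave 1, and 0 with scaling, single spots, additive terms, the disagreeing array left out or the letter block, 2 with robust eBayes or at 0.10, and 3 with 1 component removed. CCH against control gave 0, and 1 with 2 components removed. The control ratio gave 1, and 2 without centring, 33 with quantile normalization, 21 with scaling, 8 with units on at least 9 arrays, 2 at 0.10, and 80 and 25 with 1 and 2 components removed. The ratio over all arrays gave 2845, and 1825 with the letter block, 4282 and 4598 with 1 and 2 components removed and 1890 with 1 mean for all arrays.

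At 1 week CCH gave 1 unit with quantile normalization in place of 0. At 2 weeks CCH gave 2, and 1 with units on all arrays, 7 with arrayWeights, and 0 with the disagreeing array left out or regrouped, the letter block or 1 or 2 components removed. At 4 weeks CCH gave 0, and 2 with units on all arrays, 4 with the disagreeing array regrouped, 33 at 0.10, and 1 and 2 with 1 and 2 components removed. At 2 weeks CIH gave 1, and 3 with scaling, 157 with arrayWeights, and 0 with single spots or 1 or 2 components removed. At 4 weeks CIH gave 0, and 7 with quantile normalization, 3 with the disagreeing array regrouped, 2 at 0.10 and 1 with 2 components removed. The F test for duration gave 1 at 0.10 in place of 0.

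Gene lists past the threshold numbered 0 in all 5 comparisons with the correlation estimated, and 0 in 4 of them with the exact tests. The ratio over all arrays kept 3 with the exact test, which there compares list medians with 0 and not with other genes. The fry test was run on the units with a value on all arrays, so on 25 lists and fewer members than camera, and its counts differ from camera's in genes as well as in test. In 1 direction it called 2 lists in the control ratio, 6 over all arrays and 0 in each hypoxia comparison, and its mixed form 1, 20, 0 (CCH against control), 1 (CIH against control) and 0 (CCH against CIH). In the control ratio 8 lists became 3 with quantile normalization, 3 with scaling, 5 with units on all arrays and 2 with 2 components removed. In CCH against control 2 became 0 with scaling or units on all arrays, 4 with the disagreeing array regrouped, 7 with the letter block and 4 with 2 components removed. In CIH against control 4 became 2 with the disagreeing array left out and 7 with 2 components removed. In CCH against CIH 6 became 3 with scaling and 2 with the letter block. The correlation of the 2 responses, 0.575, became 0.497 with the letter block, and 0.106 or 0.0898 with split controls.

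With each array left out in turn, the counts ranged from 1 to 34 in the control ratio, 1981 to 3178 over all arrays, 0 to 1 for CCH against control, 1 to 305 for CIH against control and 0 to 196 for CCH against CIH. They ranged from 0 to 2, 0 to 3 and 0 to 32 for CCH at 1, 2 and 4 weeks, from 0 to 2, 0 to 6 and 0 to 162 for CIH, from 0 to 2 for controls at 4 weeks against 1 and from 0 to 1 for the F test. The lists ranged from 2 to 8 in the control ratio, 2 to 4 over all arrays, 0 to 7 for CCH against control, 2 to 11 for CIH against control and 3 to 11 for CCH against CIH. The differences in spread ranged from 0.0718 to 0.133, 0.0453 to 0.104 and -0.000785 to 0.0585. Where an array left out leaves 1 in its group, that array is assumed to vary like the other groups. Of the values of named genes, 3509 with an array left out and 2990 in the other alternatives kept their direction and side of the threshold, 74 and 87 newly passed and 36 and 37 no longer passed. Another 162 values, of genes that passed in neither fit, changed sign without being counted as reversed, the largest 0.46 for Nppb in CCH against CIH with 2 components removed.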

Other observations

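Among the tests of this part, that of the dyes was chosen only after the result was seen, as were the genes named in the next paragraph.

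Over all arrays, 6 of 27 genes of the extracellular matrix fell and 1 rose over all genes (7 and 2 adjusted over the list alone), and the list did not pass the camera test (adjusted p = 0.471). Col3a1 was the one that rose over all genes (0.19, adjusted p = 0.039, 12 of 18 arrays). Among those that fell were Col6a1, a chain of collagen VI (-0.36, limma adjusted p = 0.000172, 18 of 18 arrays), the proteoglycans Bgn (-0.39, adjusted p = 0.000562, 17 of 18) and Dcn (-0.29, adjusted p = 0.0019, 12 of 18) and the intermediate filament gene Vim (-0.34, adjusted p = 0.0138, 14 of 18). Of 65 genes of oxidative phosphorylation 21 fell and 3 rose (23 and 3 adjusted over the list alone, camera list adjusted p = 0.0539). Of 38 genes on the proteasome list 13 fell and 3 rose (15 and 3 adjusted over the list alone, camera list adjusted p = 0.382).

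The ratio of Pgrmc1 was -1.67 and -1.11 on the arrays of CCH at 2 weeks and between -0.40 and 0.57 on the others. Of the 2 arrays of CIH at 1 week, replicate 1, whose labels disagree, shared its pattern of spots without a value most closely with the other array of its title (r = 0.79 across spots, rank 1 of 17). Its ratios correlated at r = 0.284 across genes with that array (rank 10), at 0.528 and 0.398 with the arrays of CCH at 2 weeks named by its sources and most with CIH at 4 weeks replicate 1 (0.604). Across genes, arrays of the same group correlated with a median r of 0.284 (-0.0764 to 0.711, 9 pairs) and arrays of different groups with 0.142 (-0.54 to 0.761, 144 pairs).

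The 283 units lower under CIH at an adjusted p under 0.10, erythroid genes left out, may move together with red-cell transcripts. In the differences between the 2 arrays of each control and CCH group, which hold no CIH array, the median correlation of these units with the erythroid mean was 0.887 over 6 differences (93.9% of 280 units over 0.5), against -0.053 for the other units. For the erythroid genes, which make up that mean, it was 0.782 (62.5% of 16 over 0.5). These units thus followed the mean more closely than the erythroid genes did. Without the CCH pair at 2 weeks the medians were 0.882 for these units, -0.0614 for the other units and 0.567 for the erythroid genes. The units and the erythroid genes therefore shared a pattern between arrays of 1 condition, where CIH is absent. Whether that pattern comes from blood in the hearts or from another property of the arrays was not tested.

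Chance is not excluded for the numbers of calls between hypoxia and control. For CCH against control the 0 calls by limma are reached by all 100 of 100 splits within duration by definition, which tests nothing (highest of the others 822). At an unadjusted p under 0.05, 33 of 100 splits gave as many as its 649 units, with 2965 as the highest of the others. Its 2 lists were reached by 82 of 100 splits, with 16 as the highest. For CIH against control, 11 of 100 splits gave at least 1 call, with 2624 as the highest of the others, and 72 of 100 gave at least 4 lists, with 15 as the highest. Splits with that many calls point to a structure of the samples that the conditions do not follow.

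The ratios off 0 over all arrays could hold dye effects as well as sex. In 2630 genes with at least 2 spots, the mean ratios of 2 spots of a gene correlated at r = 0.215 across genes, between the bounds set for a bias of single spots (under 0.1) and against it (over 0.3), and 58.8% had the same sign. Among the 623 of them called over all arrays r was 0.519 and 89.7% had the same sign, but these genes were picked for their mean. A dye effect that all spots of a gene share cannot be told apart from sex, because 0 arrays held the female heart in Cy5. A difference between male and female hearts stays open for all of these genes, with Eif2s3y as the gene that the Y chromosome sets.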
